A study of Homo sapiens with 10 samples.

How the data were processed

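Total RNA of Li-7 hepatocellular carcinoma cells, 5 samples given PBS and 5 given galectin-9, was labelled with the dye Hy5 and hybridised to one-colour miRNA arrays, per the labels. The deposited scanner tables give the intensity of each spot on a linear scale, as a foreground median, a foreground mean and a local background median, per the file headers, with no normalization. Scanner, image software and their versions are not given in the sources used here. Each array holds 3200 spots, of which 2019 are miRNA probes, 925 blank and 16 spiked-in controls, and 15 miRNA probes name several miRNAs. The authors also deposited a table of processed intensity values. Set against the scanner tables, it has the ranks of the quantile normalized spot medians less a constant of 207 intensity units, close to the mean blank threshold, and each of its columns has a median of 81.7. It gives values for 392 miRNAs, the same as those found here to be detected on all 10 arrays. No genome build is named, so no coordinates are given. Identifiers of the miRNAs are those of the array's design.

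Groups were taken from the sample labels. A miRNA was detected on an array where its foreground median exceeded the mean plus 2 SD of the blank spots, with the top and bottom 5% of blanks trimmed. Foreground medians were corrected with normexp (offset 50) on the local background, transformed to log2 and quantile normalized over all 2019 miRNA probes, of which 61.4% were detected on at least 5 arrays. Those 1239 were tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3, galectin-9 minus control, two-sided, without a block, and called at a Benjamini-Hochberg adjusted p under 0.05. Saturated spots were kept. Other control spots were left out of the tests. A log2 difference under 1e-09 in size was counted as neither higher nor lower.

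The 17 miRNA lists (let-7 family, miR-17 clusters, p53-induced, liver, raised or lowered in hepatocellular carcinoma, apoptosis, miR-200 family, inflammation, hypoxia, miR-371 to miR-373 and C19MC, C14MC, blood cells, stromal and endothelial, muscle, neural, and fragments of other RNAs) were tested with camera at a preset correlation of 0.01, and an exact permutation test was run on the mean of each list over the arrays. The miRNAs named are the 12 largest rises and 12 largest falls with adjusted p under 0.05 and the same direction in every leave-one-out fit (all of them where fewer passed), the 5 brightest, up to 4 tested members of each list with the smallest p, and miR-1246. Lists, groups, tests, this rule and the alternatives were fixed before the data were examined, except where the text says otherwise.

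Alternatives were no background correction, plain subtraction with a floor of 16, a normexp offset of 16, scaling by the median of miRNAs detected on all arrays or by the 75th percentile, cyclic loess, no normalization, no filter, detection on all 10 arrays, the authors' processed values, an intensity trend with robust eBayes, array weights, a block for the replicate number, an adjusted p under 0.01, other list tests, a threshold of 3 SD, and each array left out in turn. Added after seeing the data were scaling to the spiked-in spots, the spot mean as the signal, a block for the pair of array positions, and adjustment over the 392 miRNAs detected on all arrays. A value that is past the threshold in neither fit counts as kept whatever its sign. The files give no slide or scan date, and each miRNA has 1 probe, so the alternatives for a slide block and for separate probes were not run.

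The tests were tried on simulated data for 1239 miRNAs. Of 50 miRNAs changed by a log2 of 0.3, 28 were recovered, 41 of 50 at 0.5, 49 of 50 at 0.8 and 50 of 50 at 1.2, with 6 false calls among 174. The data gave only 6 calls, and the adjusted threshold is harder to pass with fewer calls. The recovery of changes of these sizes in the data may therefore be lower. With no change simulated, 0 lists and 0 miRNAs were called. Normalized values were drawn independently for each miRNA, so the simulation could not show false list calls that come from correlated members or from the normalization. Neighbouring miRNA genes were taken from the RefSeq table for GRCh38.p14. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.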

Results

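Li-7 is a cell line from a human hepatocellular carcinoma, and galectin-9 is a secreted lectin that binds beta-galactosides. Cells were cultured for 24 h and then received either galectin-9 at a final concentration of 0.3 µM or the PBS vehicle for a further 24 h. Total RNA was read on 10 one-colour arrays, 5 of control cells and 5 of galectin-9-treated cells, each with 1 probe for each of 2019 miRNA entries. The comparison asks which miRNAs differed between treated and control cells in a study of growth suppression by this lectin. The labels do not say that the replicates were separate cultures, so the p-values measure the spread between these samples, which may be technical. On single arrays, between 725 and 1494 miRNAs lay above the blank spots, and 1239 miRNAs above them on at least 5 of the 10 arrays were tested. The number of arrays limits the precision, with a median SE of 0.105 for a log2 difference.

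Arrays of galectin-9-treated cells gave more signal for miR-6131, miR-3960, miR-1237-5p and miR-6126 and less for let-7d-5p and miR-125a-5p than arrays of control cells. These 6 miRNAs, 4 higher and 2 lower, passed limma's test at a Benjamini-Hochberg adjusted p under 0.05, and 0 of them differed by 2-fold or more. Leaving out 1 array gave 4 to 11 calls, 4 to 8 higher and 0 to 3 lower. All 4 rises were of late-registered miRNAs and the 2 falls of early-registered ones, a split described under the other observations whose cause is open. The largest rise was that of miR-6131, which went from a normalized log2 signal of 8.43 ± 0.13 (SD, n = 5) in control cells to 9.32 ± 0.23 (n = 5) with galectin-9, a 1.86-fold rise (log2 difference 0.89, SE 0.11, adjusted p = 0.00179). The miRNA miR-3960, which shares a cluster with miR-2861 and is known from osteoblast differentiation, rose 1.69-fold (log2 difference 0.75, SE 0.10, adjusted p = 0.00268). For miR-1237-5p the rise was 1.45-fold (log2 difference 0.53, SE 0.067, adjusted p = 0.00179), and for miR-6126 it was 1.40-fold (log2 difference 0.49, SE 0.074, adjusted p = 0.00648). Each of these 4 miRNAs was higher on all 5 galectin-9 arrays than the control mean. Their log2 differences stayed above 0 in all 26 alternative settings. All 4 calls were lost when arrays were scaled to the spiked-in control spots, where the differences were 0.90, 0.68, 0.58 and 0.54 for miR-6131, miR-3960, miR-1237-5p and miR-6126, each with an SE of 0.28. The wider spread between arrays ended these calls (adjusted p of 0.553 for miR-6131 and 0.695 for the others).

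The 2 falls were smaller than the 4 rises on the log2 scale. With quantile normalization the growth-restraining let-7d-5p was lower by 0.36 on the log2 scale (SE 0.062, adjusted p = 0.0188), 0.780 of its control level. Its difference was -0.021 with scaling by the median of detected miRNAs (adjusted p = 0.935) and -0.14 with cyclic loess (0.602). It was above 0 without normalization (0.10) and with scaling to the 75th percentile (0.083). Its 5 control arrays share 1 value, 11.90, because quantile normalization gave them the same rank. The rising miR-3960 lay below let-7d-5p on all control arrays (11.25 to 11.56) and above it on all galectin-9 arrays (11.90 to 12.44), so their ranks crossed. The miRNA miR-125a-5p, which is known to target ERBB2 and ERBB3, fell by 0.33 (SE 0.063, adjusted p = 0.0352), to 0.795 of its control level, and was lower on all 5 galectin-9 arrays than the control mean. It stayed below 0 under every scaling tried, with -0.014 as the value nearest 0 and an adjusted p of 1 there, and its call was kept when galectin-9 replicate 3 was left out but lost without any other single array. The call of let-7d-5p was lost without control replicate 1, galectin-9 replicate 1 or galectin-9 replicate 4. Calls of both let-7d-5p and miR-125a-5p were lost with no filter (adjusted p of 0.0851 and 0.114) and with a normexp offset of 16 (0.113 and 0.120). Cyclic loess also ended the call of miR-125a-5p (-0.30, adjusted p = 0.099).

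**Figure D1:**
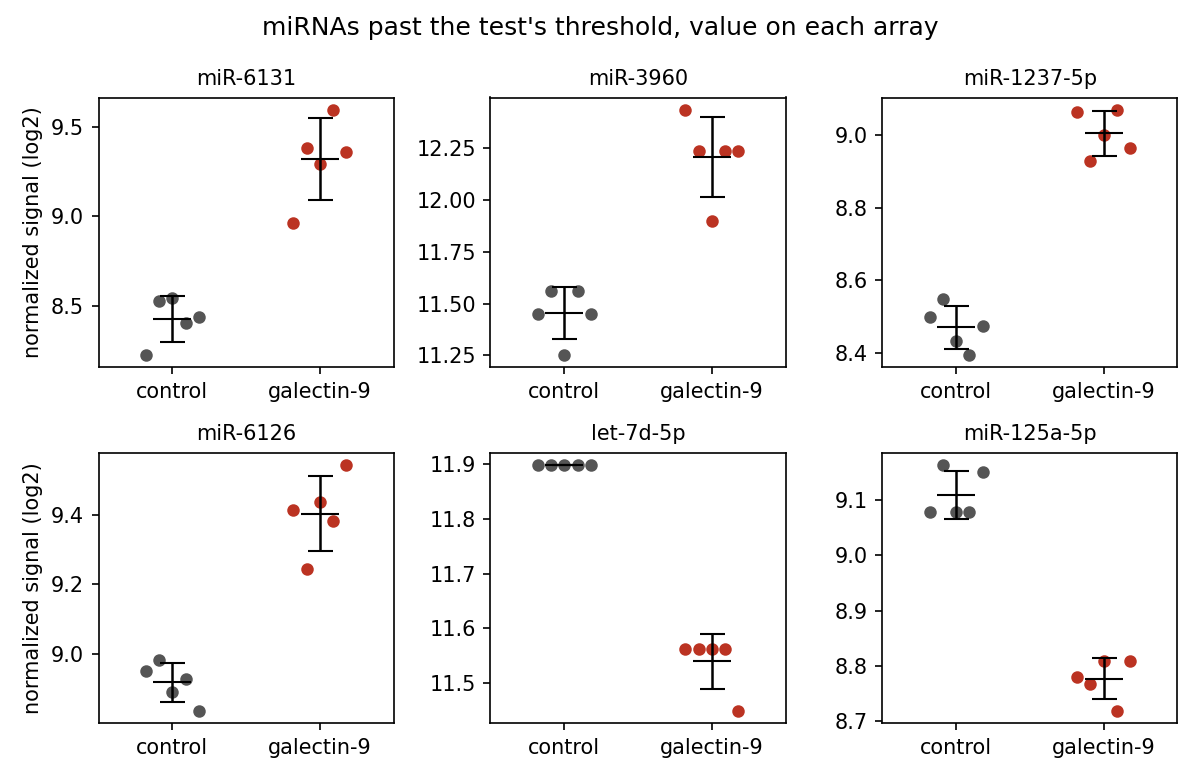
Normalized log2 signal of the 6 miRNAs past the threshold on each of the 5 control arrays (grey) and 5 galectin-9 arrays (red), with a black bar for the mean and its SD. The 4 risers sit above all control arrays after galectin-9 and the other 2 below them, except that the difference of let-7d-5p is above 0 without normalization (0.10) and with 75th percentile scaling (0.083).

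Calls split differently by direction under other scalings. With quantile normalization 66.7% of the calls were higher with galectin-9. That share was 93.5% of 31 calls when arrays were scaled by the median of the miRNAs detected on all arrays, 95.3% of 43 calls with 75th percentile scaling, 98.0% of 51 calls without normalization and 100% of 7 calls with cyclic loess. At an unadjusted p under 0.05 134 miRNAs differed with quantile normalization, 78 higher and 56 lower. The groups did not overlap for 38 of the 1239 tested miRNAs, 3.07%, where chance gives 0.794%.

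The let-7 family, which restrains growth by targeting RAS, MYC and HMGA2, was lower with galectin-9 in 9 of its 9 tested members, with a mean log2 difference of -0.19 and a camera adjusted p of 6.71e-05. With an estimated correlation the adjusted p was 0.232, and an exact permutation test over the 10 arrays gave p = 0.00794, the smallest these arrays allow, which is 0.0675 adjusted over the 17 lists. The named members have registry numbers under 3000. Of all 156 such miRNAs detected on all arrays 119 were lower, with a median of -0.084, nearer 0 than the list's mean. Adjusted over the list alone, 3 members fell, let-7d-5p, let-7i-5p and let-7b-5p, of which let-7d-5p also passed over all miRNAs. The difference was -0.33 (SE 0.070, adjusted p = 0.0689 over all miRNAs) for let-7i-5p and -0.31 (SE 0.11, adjusted p = 0.261) for let-7b-5p, and let-7c, which passed neither way, had -0.18 (SE 0.079). The list's direction depended on the scaling, since its mean was above 0 with 75th percentile scaling (0.074) and without normalization (0.094), and with scaling by the median of detected miRNAs (-0.030) or by the spiked-in spots (-0.19) camera's direction turned upward with adjusted p of 0.697 and 0.705.

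The miR-17 clusters, growth-promoting and driven by MYC and E2F, were lower in 12 of 13 tested members, with a mean log2 difference of -0.095 and a camera adjusted p of 0.0229 (adjusted p = 0.243 with an estimated correlation, and 0.077 in the exact permutation test). Adjusted over the list alone, 0 members passed limma's test. The named members have registry numbers under 3000, and of all 156 such miRNAs detected on all arrays 119 were lower, with a median of -0.084 near the list's mean. The largest difference was that of miR-92a-3p, -0.20 (SE 0.075, adjusted p = 0.315), followed among the named members by miR-19a-3p, -0.16, miR-18a-5p, -0.16, and miR-20a-5p, -0.14. This list turned upward with scaling by the median of detected miRNAs (0.031), with 75th percentile scaling (0.14) and without normalization (0.16), and camera's direction was also upward with the spiked-in spots, where the mean was -0.13. Camera's adjusted p in these settings was 0.0587 to 0.132, so the call was lost.

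Among miRNAs described as lowered in hepatocellular carcinoma, 15 of 20 tested members were lower, with a mean of -0.076 and a camera adjusted p of 0.0457 (adjusted p = 0.243 with an estimated correlation, and 0.077 in the exact permutation test). In it miR-125a-5p fell over all miRNAs, and adjusted over the list alone 2 members fell, miR-125a-5p and miR-424-5p, a relative of miR-15 and miR-16 (-0.34, SE 0.082, adjusted p = 0.0748 over all miRNAs). The list of miRNAs described as raised in this carcinoma did not pass, with 13 of 18 members lower, a mean of -0.070 and a camera adjusted p of 0.0582 (0.077 in the exact permutation test), and 0 members passed adjusted over the list alone. It passed camera without control replicate 5 (adjusted p = 0.0451), without galectin-9 replicate 1 or 3 (0.0464 for each) and with the spot mean as the signal (0.0435). In the raised list miR-224-5p had -0.21 (SE 0.075) and miR-301a-3p -0.21 (SE 0.084). The apoptosis list, whose members are described as targeting BCL2-family and other anti-apoptotic transcripts, was lower in 15 of 20 members, with a mean of -0.069 and a camera adjusted p of 0.0457 (adjusted p = 0.245 with an estimated correlation, and 0.135 in the exact permutation test). Adjusted over the list alone 1 of its members fell, miR-15b-5p, known to target BCL2 (-0.31, SE 0.079, adjusted p = 0.0844 over all miRNAs), and it shares 7 tested members with the lowered list. The lowered list kept its call in 10 of 28 alternatives and the apoptosis list in 7. Named members of both lists have registry numbers under 3000, and of all 156 such miRNAs detected on all arrays 119 were lower (median -0.084). The means of the lowered and apoptosis lists were above 0 with 75th percentile scaling (0.063 and 0.068) and without normalization (0.083 and 0.088). For both, camera's direction was upward with scaling by the median of detected miRNAs (-0.042 and -0.037) and by the spiked-in spots (-0.21 and -0.20), short of the threshold (adjusted p of 0.697 and 0.705). The mean of the raised list was above 0 with 75th percentile scaling (0.13), without normalization (0.15) and with scaling by the median of detected miRNAs (0.026).

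Among p53-induced miRNAs 7 of 12 were higher, with a mean of 0.054 and a camera adjusted p of 0.365. Adjusted over the list alone 1 member rose, miR-1246, a p53-induced entry that overlaps U2 snRNA, with a log2 difference of 0.42 (SE 0.092), an adjusted p of 0.0692 over all miRNAs and higher values than the control mean on all 5 galectin-9 arrays. Over all miRNAs it passed in 9 of 26 alternatives (adjusted p from 0.0045 to 0.695). With the authors' processed values its difference was 0.87 (adjusted p = 0.00773). Those values are intensities less a constant of 207 units, which widens the log2 differences of dim miRNAs. The size of 0.87 is therefore not comparable with that of 0.42. The list of entries that overlap U2 snRNA, tRNA or rRNA, whose probes also read fragments of those RNAs, held 6 higher and 3 lower members and 3 with the same value on all arrays (miR-4454, miR-5100 and miR-1260b). It had a mean of 0.079, a camera adjusted p of 0.233 and an exact permutation p of 0.00794 (0.0675 adjusted over the lists). Adjusted over the list alone miR-1246 and miR-663a (0.27, SE 0.093) rose and miR-1260a (-0.23, SE 0.071) fell, though the difference of miR-1260a was above 0 with 75th percentile scaling (0.054) and without normalization (0.074). Liver-enriched miRNAs had 6 of 10 members higher, with a mean of 0.035 and a camera adjusted p of 0.400. Their miR-148a-3p had 0.24 (SE 0.085) and miR-194-5p 0.16 (SE 0.071), and the former was below 0 with the spiked-in spots (-0.023). The hypoxia list had 4 of 8 members higher, a mean of 0.026 and a camera adjusted p of 0.655, with 0.13 (SE 0.080) for the hypoxia-induced miR-210. The hypoxia, p53-induced, liver and RNA fragment lists were called upward relative to other miRNAs when scaled by the median of detected miRNAs (camera adjusted p of 0.000323, 0.0202, 0.0282 and 0.0124), with 75th percentile scaling (0.00063, 0.0171, 0.0171 and 0.0171) and without normalization (0.00018, 0.0161, 0.0161 and 0.0161). With the spiked-in spots, where the median of all tested miRNAs was -0.25, their means were 0.018, -0.084, -0.085 and -0.062, and camera called the hypoxia, p53-induced and fragment lists upward (0.00157, 0.0354 and 0.0128) but not the liver list (0.0509). These settings differ only by a constant for each array, so they repeat 1 contrast of a list with the other miRNAs. Of the 1239 tested miRNAs 392 were detected on all arrays, while the hypoxia and fragment lists were bright, with control means of 10.4 and 10.6.

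Lists of other cell types and programmes did not pass camera's threshold with all arrays. The means were 0.026 for the epithelial miR-200 family (adjusted p = 0.655), -0.028 for NF-kB- or interferon-induced miRNAs (0.655), -0.049 for the stem cell and placental clusters miR-371 to miR-373 and C19MC (0.248), and -0.017 for C14MC, the imprinted DLK1-DIO3 cluster (0.655). Markers of blood cells had a mean of -0.058 (adjusted p = 0.365), those of stromal and endothelial cells -0.066 (0.349), those of muscle -0.15 (0.105) and those of neurons -0.0062 (0.957). No member of these 8 lists passed adjusted over the list alone, and all 4 tested muscle markers were lower, with -0.24 for miR-133a and -0.25 for miR-1. Of the other markers, miR-451a had 0.11, miR-223-3p -0.15, miR-126-3p -0.16 and miR-200b-3p 0.12. Without normalization the means of the inflammation, C14MC, stromal and neural lists were above 0 (0.031, 0.023, 0.015 and 0.035), and with the spiked-in spots that of the miR-200 family was below 0 (-0.22). The muscle list passed camera without control replicate 5 (adjusted p = 0.0451). Fry, which tests whether a list moves on balance 1 way and does not compare it with other miRNAs, called 7 of the 17 lists (let-7, miR-17, the lowered and raised carcinoma lists, RNA fragments, muscle, and stromal and endothelial, the last 5 each with an adjusted p of 0.043), camera with its preset correlation 4, and camera with an estimated correlation 0.

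**Figure D2:**
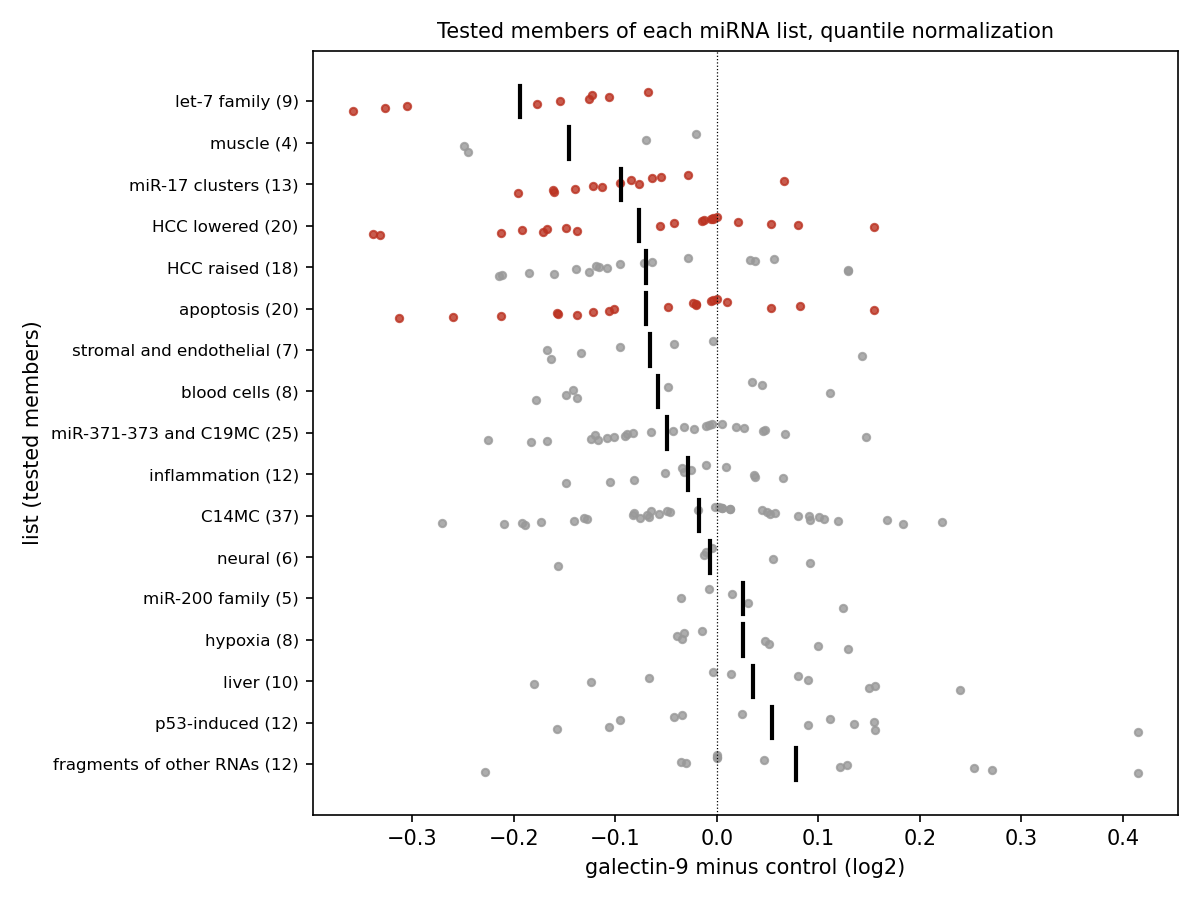
Galectin-9 minus control log2 difference of each tested miRNA (points) in 17 lists, with the list mean as a black bar and the number of tested members beside the list's name (HCC stands for hepatocellular carcinoma). Lists past camera's threshold with its preset correlation are red, the let-7 family lowest at a mean of -0.19, but the means of these 4 lists are above 0 with 75th percentile scaling and without normalization.

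The brightest probes were those of miR-4454, miR-5100, miR-1260b, miR-4284 and miR-4286. The spot of miR-4454 was saturated on all 10 arrays, so no fold is given for it. Quantile normalization gave miR-5100 and miR-1260b the same value on all arrays, and miR-4284 and miR-4286 had 0.031 and -0.031 (adjusted p = 0.939 for both).

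The number of detected miRNAs differed by less than the spread between arrays. Control arrays detected 1198 ± 272 (SD, n = 5) and galectin-9 arrays 1124 ± 241 (n = 5), a difference of -73.2 in a two-sided exact permutation test with p = 0.643. The median local background was 143 ± 7.73 intensity units on control arrays and 132 ± 10.0 on galectin-9 arrays (exact permutation p = 0.119, and 0.824 adjusted over 7 array measures). Spiked-in control spots had a mean log2 signal of 14.45 ± 0.30 and 14.74 ± 0.48 (exact permutation p = 0.294), and scaling arrays to them moved the median log2 difference of the tested miRNAs to -0.25. These permutation tests ignore the replicate numbers. Between arrays of 1 number the galectin-9 array had lower local background and higher spiked-in signal in all 5 pairs. The exact sign-flip p was 0.0625 for each, the smallest 5 pairs allow, in a test chosen after seeing the data. A systematic difference between the arrays of the groups is thus not excluded. Array positions 1 and 3 held control samples and positions 2 and 4 galectin-9 samples, so position parity and treatment cannot be told apart.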

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

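Samples far from the other 4 of their group were looked for in 192 sets of 5 values, and 9 were found, where chance gives about 1 in 20. For 4 miRNAs the other 4 arrays shared 1 tied rank value: let-7d-5p was 11.45 in galectin-9 replicate 5 against 11.56, miR-16-5p was 11.31 in galectin-9 replicate 4 against 11.18, and in control replicate 2 miR-4284 was 13.65 against 13.80 and miR-4286 was 13.80 against 13.65. In control replicate 4, miR-18a-5p was 9.17 against 8.85 to 8.93 and miR-15a-5p was 9.06 against 8.70 to 8.78. In control replicate 3, miR-193b-3p was 8.28 against 8.49 to 8.57.

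Blank spots of galectin-9 replicate 3 had an SD of 16.8 intensity units against 8.99 to 10.8 on the other galectin-9 arrays, and this array also detected the fewest miRNAs, 725. Without it 11 miRNAs were called, 8 higher and 3 lower. The mean of later-registered minus early-registered miRNAs, described under the other observations, was -0.33 in control replicate 4 against -0.21 to -0.17 on the other control arrays. Among 38 kinds of control spot outside the comparison, S-Probe1013 was brighter on every galectin-9 array than on every control array, by 0.26 on the log2 scale (exact permutation p = 0.00794, adjusted p = 0.302).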

How the results depend on the processing

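Alternatives chosen only after seeing the data were scaling to the spiked-in spots, the spot mean, the position pair block and adjustment over the miRNAs detected on all arrays. The rises of miR-6131, miR-3960 and miR-1237-5p kept their direction in 26 of 26 alternatives and their call in 25, and miR-6126 kept its call in 24, while let-7d-5p kept its call in 13 and miR-125a-5p in 7. The let-7 family list kept its call in 23 of 28 alternatives, the miR-17 clusters in 20, the lowered carcinoma list in 10 and apoptosis in 7. The alternatives share arrays and most keep the quantile normalization, so these counts are not independent support. Past the threshold in some alternatives were miR-1246 (9 of 26), let-7i-5p and miR-15b-5p (5 each) and miR-424-5p (4), and the raised carcinoma list (5 of 28). Many miRNAs lay close to the blank spots, with 392 of 2019 above them on all arrays. Except for the filter, the adjustment and the spiked-in spots, the cause of each difference below was not tested.

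The main count was 6 miRNAs changed (4 higher, 2 lower, 0 by 2-fold) and 4 lists. Without background correction it was 30 (22 higher, 8 lower) with 2 lists. Plain subtraction, an offset of 16 and no filter each gave 0 lower and 2 lists. Scaling by the median of detected miRNAs gave 31 (29 higher), 1 of them by 2-fold, and scaling by the 75th percentile 43 (41 higher), 1 by 2-fold. Without normalization 51 changed (50 higher, 1 lower), 1 by 2-fold, and cyclic loess gave 7 higher and 0 lower. Detection on all 10 arrays gave 39 (27 higher, 12 lower) and 1 list. The p of the test over 1239 miRNAs, adjusted over the miRNAs detected on all arrays alone, gave 32. Restricting the adjustment to those miRNAs thus accounts for most of that gain. The authors' processed values gave 20 (15 higher, 5 lower), 2 by 2-fold, and 1 list. An intensity trend with robust eBayes gave 41 (30 higher, 11 lower), array weights 2 lists, an estimated correlation 0 lists and fry 7. Spiked-in scaling gave 0 changed, 0 higher and 0 lower, as the median SE rose from 0.105 to 0.280 while the 4 risers had 0.90, 0.68, 0.58 and 0.54 and let-7d-5p and miR-125a-5p -0.19 and -0.30, the spot mean 17 (13 higher, 4 lower), and the position pair block 1 lower.

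Camera no longer called the let-7 family, miR-17, lowered carcinoma and apoptosis lists under 4 settings, where its direction for them turned upward (adjusted p from 0.0587 to 0.705). These settings differ only by a constant for each array, so the difference of a list from the other miRNAs is the same in all 4. The mean log2 differences of the lists were -0.030, 0.031, -0.042 and -0.037 with the median of detected miRNAs, 0.074, 0.14, 0.063 and 0.068 with the 75th percentile, 0.094, 0.16, 0.083 and 0.088 without normalization, and -0.19, -0.13, -0.21 and -0.20 with the spiked-in spots. The difference of let-7d-5p reversed to 0.083 with the 75th percentile and to 0.10 without normalization.

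Leaving out each array in turn gave 4 to 11 changed miRNAs (11 without galectin-9 replicate 3), 4 to 8 higher, 0 to 3 lower, 0 to 0 by 2-fold, and 1 list (without control replicate 1) to 6 lists (without control replicate 5). The difference in detected miRNAs ranged from -168 without control replicate 4 to 26.7 without galectin-9 replicate 3, and was -70.0 with the threshold of 3 SD.

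With the replicate number as a block 3 miRNAs were called, 0 of them lower, and 2 lists. The calls of miR-6126 (adjusted p = 0.130), let-7d-5p and miR-125a-5p (0.164 for both) were lost, as were those of the lowered carcinoma and apoptosis lists (0.0591 for both), and those of miR-6131, miR-3960 and miR-1237-5p were kept. Whether the numbers pair the samples is open: deviations from the group means correlated at 0.00038, 0.122, 0.00813, -0.0694 and 0.0832 for the 5 numbers, and 4 of 10 arrays correlated best with their own number. Arrays of 1 number lay at positions 1 and 2 or 3 and 4. In all 5 pairs the galectin-9 array had lower local background (by 7 to 14 intensity units in size), a lower median miRNA signal and a higher spiked-in signal (exact sign-flip p = 0.0625 for each, the smallest 5 pairs allow, chosen after seeing the data).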

Other observations

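The tests of odd against even positions, of the slope along positions, of late against early entries at equal signal and of other splits of the arrays were chosen after the results they bear on had been seen, as were the class limits of the registry numbers and the miRNAs named here outside the fixed rule. Among the 392 miRNAs detected on all arrays, tested on their own, 39 passed, 27 higher and 12 lower with galectin-9. Besides the miRNAs already named as risers, the rises included miR-3621 (0.63), miR-4294 (0.54), miR-1234-5p (0.52), miR-4516 (0.38), miR-5787 (0.33), miR-762 (0.34), miR-6090 (0.35) and miR-1908 (0.32), each above 0 under all 6 scalings. The falls included miR-30c-5p (-0.29), miR-320a (-0.26), miR-99b-5p (-0.26), let-7i-5p (-0.33), miR-15b-5p (-0.31) and miR-424-5p (-0.34). Under 6 scalings let-7i-5p (-0.33 to -0.016) and miR-424-5p (-0.34 to -0.038) stayed below 0, while without normalization miR-30c-5p had 0.0069, miR-15b-5p 0.029, miR-320a 0.12 and miR-99b-5p 0.16. The cluster of miR-99b, let-7e and miR-125a had differences of -0.26 for miR-99b-5p, -0.11 for let-7e-5p (0.13 without normalization) and -0.33 for miR-125a-5p. Of its other arms, miR-125a-3p had -0.30 (0.032 without normalization), let-7e-3p 0.14 (-0.15 with the spiked-in spots) and miR-99b-3p 0.053 (-0.20 with the spiked-in spots), and the cluster partners miR-3960 and miR-2861 had 0.75 and 0.23.

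Of 100 splits of the 10 arrays into groups of 5, 1, the real one, gave 6 or more changed miRNAs, against at most 1 in any other split. The same held for the 4 higher miRNAs (1 of 100 splits, at most 1 elsewhere) and the 39 among miRNAs detected on all arrays (1 of 100, at most 1 elsewhere). For the 4 lists, 2 of 100 splits gave as many, and the highest other split also called 4. For the 2 lower miRNAs the count was 1 of 100 with at most 0 elsewhere. The higher and lower counts add nothing of their own, since the other splits made at most 1 call in all. The share of splits with as many was under 0.05 for the changed miRNAs and for the lists. For the lists this is weak, since none passed the exact permutation test after adjustment (lowest adjusted p of 0.0675). The splits separate treatment neither from position parity nor from a difference between cultures, as the labels do not say that the replicates were separate cultures.

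The called miRNAs divided by when they entered the miRNA registry. Of the 39, 26 of the 27 higher had registry numbers of 6000 or more and 10 of the 12 lower had numbers under 3000. In the main test all 4 rises had numbers of 6000 or more and the 2 falls numbers under 3000. Among all 392, 94 of 150 late entries were higher and 53 lower with galectin-9 (median log2 difference 0.078) against 37 higher and 119 lower of 156 early entries (median -0.084). Per array, the mean of late minus early entries was -0.22 ± 0.060 (SD, n = 5) in control cells and -0.035 ± 0.068 (n = 5) with galectin-9, a difference of 0.19 (exact permutation p = 0.00794, the smallest possible). It was also 0.19 with cyclic loess and was 0.17 with no normalization, from which scaling each array by a constant cannot move it. The early entries alone had -0.078 with quantile normalization (exact permutation p = 0.0159) and 0.071 with 75th percentile scaling (p = 0.206), with p under 0.05 in 2 of 6 scalings. The late entries alone were above 0 with p under 0.05 in 5 of 6 scalings (0.11 to 0.26, largest exact permutation p = 0.0238), and had -0.031 (p = 0.921) with the spiked-in spots.

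The background correction does not account for all of the difference, which was 0.187 with it and 0.124 without it (exact permutation p = 0.0159). Its size depends in part on the correction. An effect of the background itself stays open, since the uncorrected signal holds the background. The signal of the spiked-in spots is argued against, since regression on it left 0.185. A gradient along the array positions is argued against as well: within groups the slope was -0.0041 per position (SE 0.022) where the group difference would need 0.187, and the 3 galectin-9 arrays at position 2 exceeded the 2 control arrays at position 3 by 0.207 (0.142 without control replicate 4 and 0.271 without control replicate 2), past the bound set beforehand, their summed SDs of 0.177. A signal trend shared by late and early entries, whose mean signals were 8.29 and 8.41, is argued against, since beside a spline of signal the difference was 0.202 (exact permutation p = 0.00794). A part for signal level stays open, as the difference was 0.28 in the 131 brightest miRNAs (exact permutation p = 0.00794), 0.17 in the next 130 (p = 0.0397) and 0.0767 in the 131 dimmest (p = 0.0397), short of the 0.1 set beforehand. Odd against even position cannot be told apart from treatment, as 0 of the 2 parities held both groups. The treatment, position parity, signal level and background in part, and base composition, which was not analysed here, may each account for the pattern.

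It was asked whether the dimmer arm of a hairpin moved against the brighter arm, as a change in processing or stability of mature miRNAs might give. Over 43 hairpins with both arms detected on all arrays, the minor (dimmer) minus major (brighter) arm differed between groups by -0.00165 (exact permutation p = 0.952, SD 0.050 and 0.044 within groups), which does not exclude a small shift. The arms were ranked by the signals of different probes, which need not rank them by abundance, so the test holds only for that ranking. In single hairpins the largest gap was that of miR-1234, with 0.52 for miR-1234-5p and -0.12 for miR-1234-3p.

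Neighbouring miRNA genes might change together if they share a transcript. In 84 pairs within 10000 bases, the mean absolute difference between the log2 changes was 0.132, against 0.158 when changes were shuffled within registry classes 10000 times (p = 0.052, permutation), so the threshold of 0.05 was missed and a shared change was neither shown nor excluded. Pairs that share a miRNA are not independent. Strand was not used to form the pairs, so some may lie on opposite strands and share no transcript.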
